A study of Mus musculus with 56 samples.

How the data were processed

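The arrays measured total RNA of splenic CD4 or CD8 T cells, isolated with a magnetic negative selection mix, as biotin-labelled cRNA on an Affymetrix mouse array with 45101 probe sets, 64 of them controls. Human arrays named in the series design were not used. Per the file headers, the deposited Signal is an intensity from an Affymetrix statistical expression analysis of 1 array at a time, and the values show no scaling between arrays. By those headers the authors' detection p-value of each probe set on 1 array gave its Present, Marginal or Absent call. The deposited series table held the same signals (largest difference 0). The software version was not stated.

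The choices below on values, filters, lists, tests and named genes were fixed before the data were examined, except where stated. Arrays were to be used as deposited if their 2% trimmed means lay within 5% of their median. They did not, so the signals were quantile normalized over all 56 arrays, and log2(signal + 9) was analysed, 9 being 0.1 of the median trimmed mean of 94.2 after rounding. A probe set entered the fit of a cell type if it was called Present on at least 4 of its arrays. Of the probe sets 34945 carry 1 gene symbol, 932 several and 9160 none, and those without 1 symbol were left out of the comparisons. Each gene was represented by its probe set with the highest mean, which left 11454 genes in CD4, 11367 in CD8 and 10893 in both. The Present calls ranged from 26.7% to 48.9% of the probe sets per array.

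For each cell type limma 3.58.1 (lmFit and eBayes, R 4.3.3) was fitted to all 28 arrays with 4 groups, so that the group of 4 mice shared the estimate of spread. The contrasts were CLL minus WT, CLL minus healthy transgenic, healthy transgenic minus WT and IV-CLL minus healthy transgenic. A fit of all 56 arrays with 8 groups tested the CD8 minus CD4 difference of the CLL minus WT change. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Within 1 cell type only CLL minus WT and IV-CLL minus healthy share no arrays, so relations between contrasts of 1 cell type are given only for these. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the values, and matplotlib 3.10.9 drew the figures.

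There were 27 gene lists tested with camera (correlation 0.01, and again with an estimated correlation), adjusted over the lists of a comparison, and with fry. Other settings used 0.01 only. They cover the actin cytoskeleton, vesicle trafficking, cytotoxic effectors, helper differentiation, naive T cells, and memory and activation. They also cover inhibitory receptors and exhaustion, regulatory T cells, follicular helper T cells, T-cell receptor signalling, MAPK and NF-kB feedback, cell cycle, interferon response, apoptosis, mitochondrial respiration, glycolysis and heat shock. A technical list holds immediate-early genes, and lists of other cells cover B, plasma, dendritic, NK and erythroid cells, monocytes, neutrophils, platelets and stroma. Some genes stand in more than 1 list, such as Prdm1, Cd200, Il10, Ifng and Ccr9. Of the 13, 14, 8 and 18 lists called in CD4 (CLL minus WT, CLL minus healthy, healthy minus WT, IV-CLL minus healthy), 1, 0, 0 and 3 held with an estimated correlation. Of the 14, 13, 5 and 22 called in CD8, 0, 0, 0 and 4 held. By fry, which tests whether a list's genes move one way on balance, 10, 8, 1 and 16 lists were called in CD4 and 10, 6, 1 and 20 in CD8. Its mixed test, for changes in either direction, called 22, 13, 0 and 20 in CD4 and 20, 14, 0 and 19 in CD8.

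Named genes followed a rule. For CLL minus WT it took the 8 largest rises and 8 largest falls among called genes outside the other-cell lists, and 4 of each for the other contrasts. From each biology list it took up to 4 called members, and from each other-cell list the 2 with the highest level, plus Cd4, Cd8a, Cd8b1, Cd3e, Tcl1, Xist and Ddx3y. The text names part of these genes, and immunoglobulin and haemoglobin genes were left out of the largest changes. Aqp9 and the genes that part WT from transgenic mice were named after their values were seen.

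Other settings chosen in advance were the deposited values, pseudocounts of 0.9 and 36, no filter, Present calls on every array of 1 group, the mean over a gene's probe sets, and only the groups compared. Others were sex, age or B-cell list mean as covariates, array weights, batch, replicate number or animal as a block, and leaving out each mouse. Batch was a fixed block in fits without the IV-CLL arrays, and a random block (duplicateCorrelation) in the IV-CLL contrasts, since no batch holds IV-CLL and another group. Chosen after seeing the data were array brightness or 4 other-cell list means (B cells, monocytes, neutrophils, erythroid cells) as covariates, leaving out the 14 dim arrays, 1 batch alone, sex from transcripts and averaging IV-CLL arrays in pairs. Whether CD4 and CD8 samples came from the same animals was checked by the correlation of their residuals. When matched by age and sex labels, 27 of 27 pairs had r over 0.1, from 0.173 to 0.796 (median 0.49), and by number 24 of 28 did. The labels joined 2 pairs of different sex by transcripts, CD4 CLL 5 with CD8 CLL 6 (r = 0.173, against 0.429 by number) and CD4 CLL 9 with CD8 CLL 5, so the animal block holds different mice there.

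The fits were tested on simulated data with known changes. For CD4 CLL minus WT 3%, 56.7% and 93.9% of genes changed by log2 0.5, 1 and 2 were recovered, with 2 false calls. For CD4 healthy minus WT these were 3%, 17.9% and 87.9%, with 10 false calls, and for the difference between the cell types 4.5%, 38.8% and 84.8%, with 2. A list shifted by -1 was called in 20 of 20 rounds, with 1 call among 500 tests of other lists. The simulated genes varied independently of each other, so this does not give the rate of false list calls in the real data. There the estimated correlation within a list reached 0.63, for neutrophil genes in the fit of the difference between cell types.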

Results

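RNA of splenic CD4 or CD8 T cells was measured on 56 mouse arrays, 28 per cell type. The mice were wild type (WT) or carried Eμ-TCL1, a transgene that drives the TCL1 oncogene in B cells and leads to a disease like chronic lymphocytic leukaemia (CLL). Each cell type had 6 arrays of WT mice (5 to 8.5 months), 12 of transgenic mice with CLL (12 to 18.5 months), 4 of transgenic mice labelled healthy (4 to 9 months) and 6 labelled IV-CLL (3 months). The labels do not say what IV stands for. Age went with the group, and no CLL mouse was as young as any other. The arrays fell into 5 scan batches. Batch 1 held WT 1 to 4 and CLL 1 to 9, batch 2 held WT 5 and 6, the 4 healthy mice and CLL 10 and 11, batch 3 held CLL 12, and batches 4 and 5 held IV-CLL mice.

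The deposited signals were not scaled between arrays. The 2% trimmed mean signal ran from 10.2 to 248, a 24.2-fold range, with a median of 94.2. It lay under 0.5 of that median on 14 arrays, 8 CD4 and 5 CD8 arrays of CLL and 1 CD8 array of IV-CLL mice. Its mean was 60.5 ± 55.2 (SD, n = 12) in CD4 CLL and 109 ± 13.9 (SD, n = 6) in CD4 WT. In CD8 arrays it was 59.6 ± 38.8 (SD, n = 12) in CLL and 93.4 ± 13.6 (SD, n = 6) in WT. The Present calls had a median of 36.6% in CD4 CLL against 46.1% in CD4 WT, and 40% against 42.6% in CD8. The actin 3' to 5' ratio, a sign of RNA quality, had a median of 1.39 (1.06 to 2.16) in CD4 CLL against 1.14 (1.13 to 1.16) in WT, and 1.25 (1.11 to 1.88) against 1.17 (1.12 to 1.28) in CD8. No fit had this ratio as a covariate. All changes below are differences of mean log2 signal after quantile normalization, first group minus second, ± SE, and are relative to the middle of the genes.

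**Figure D1:**
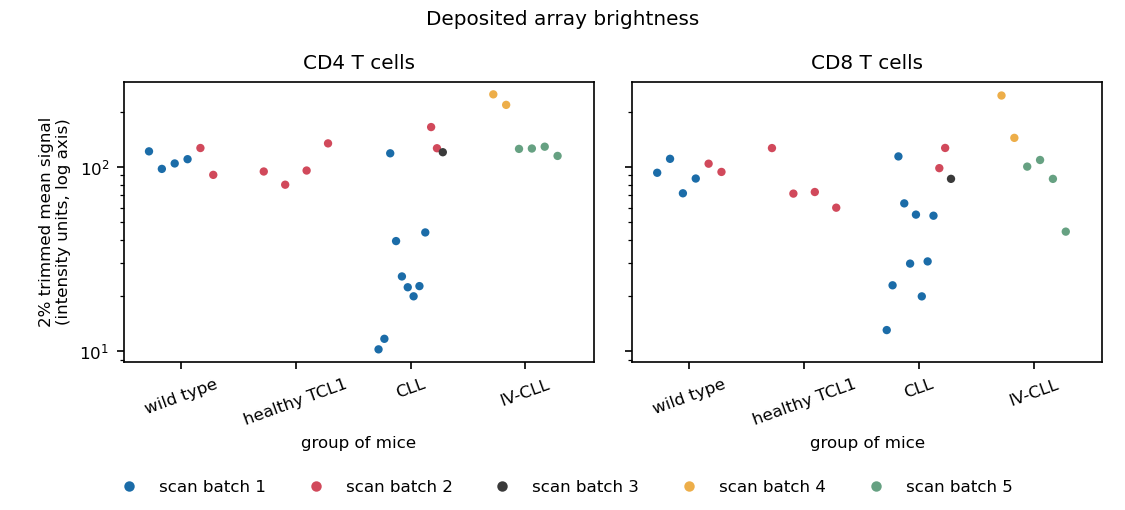
Trimmed mean signal of each of the 56 arrays as deposited (log axis, signal units), by group, with 1 point per array coloured by scan batch 1 to 5. Under 0.5 of the median of 94.2 lay 13 arrays of CLL and 1 of IV-CLL mice.

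Xist and Y-linked transcripts did not match the sex in the labels on 11 of the 56 arrays, 5 of CD4 and 6 of CD8 T cells, and sex was not used in the comparisons. The Xist difference for CLL minus WT was 0.08 ± 1.32 in CD4 and -0.40 ± 1.30 in CD8 arrays. Of genes that mark the selected cells, Cd3e differed by 0.02 ± 0.24 and Cd4 by 0.08 ± 0.31 in CD4 T cells, and Cd3e by 0.02 ± 0.29, Cd8a by -0.33 ± 0.49 and Cd8b1 by -0.03 ± 0.36 in CD8 T cells. On single arrays they lay far apart. In CD8 CLL Cd8a was 7.55, 8.36 and 8.25 on arrays 1, 2 and 8, against 10.62 to 11.79 on the others, and Cd3e was 8.50 on array 1. In CD4 CLL array 1 had Cd4 at 7.47 and Cd3e at 9.03, and array 3 had Cd8a at 10.30. The neutrophil list mean was 11.07 on CD4 and 11.92 on CD8 CLL array 1. In the CD4 arrays Cd8a differed by -0.53 ± 0.59 and Cd8b1 by -0.58 ± 0.62. The transgene's mouse counterpart Tcl1 and the Y-linked Ddx3y gave no value past the filter, and listed genes without their own probe set, such as Tcf7 and Lck, were not analysed.

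In CD4 T cells of mice with CLL (n = 12) against WT mice (n = 6), genes of naive, recirculating T cells were lower and genes of DNA replication and mitosis were higher. Of the 19 measured naive T-cell genes 12 fell and 0 rose, and 17 fell when adjusted over the list alone. The lymph node homing receptor Ccr7 changed by -2.75 ± 0.51 (adjusted p = 0.000772), the gut homing receptor Ccr9 by -2.94 ± 0.32 (1.06e-06) and the chromatin organiser Satb1 by -2.48 ± 0.39 (0.000146). Dapl1 changed by -3.58 ± 0.42 (4.32e-06) and the actin crosslinker Actn1 by -2.17 ± 0.33 (9.93e-05). The list had a median of -1.47, adjusted p = 1.79e-15, and 0.0264 with estimated correlation. Its median was -1.55 with batch as a block, -1.71 within batch 1, -0.87 within batch 2 and -1.58 with 4 other-cell means as covariates. Within batch 2 Ccr7 was -1.27, Satb1 -1.53, Dapl1 -1.55 and Actn1 -0.86.

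Of the 29 cell cycle genes 22 rose and 0 fell in the same CD4 comparison, and 25 rose over the list alone, although the list median was -0.25 on the deposited values, where the median of all genes was -1.06. The list had a median of 1.13, adjusted p = 1.12e-16, and 0.153 with estimated correlation. Its median was 1.10 with batch as a block, 1.10 within batch 1 and 0.84 within batch 2. It was 0.58 with 4 other-cell means, where 2 genes rose. The mitotic kinase Cdk1 changed by 1.83 ± 0.29 (adjusted p = 0.000146), its partner cyclin Ccna2 by 1.69 ± 0.28 (0.000187) and Mad2l1 by 1.54 ± 0.26 (0.000262).

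Of 28 cytotoxic effector genes 10 rose and 4 fell in CD4 T cells (11 and 4 over the list alone), and the list as a whole was not called (median 0.30, adjusted p = 0.11). It was called without the dim arrays, at 0.86 (adjusted p = 0.00169), with 4 other-cell means, at 0.87 (5.73e-05), and within batch 2, at 0.91 (0.0124). It was not called with batch as a block (0.24, adjusted p = 0.202, 6 genes risen) or within batch 1 (0.17, 0.588, 2 risen and 3 fallen). The granule proteases Gzmk and Gzmb changed by 3.29 ± 0.73 (adjusted p = 0.00344) and 3.00 ± 0.58 (0.00118), Cst7 by 1.53 ± 0.38 (0.00813), and the chemokine Xcl1 by -1.67 ± 0.42 (0.00916). Among 22 helper differentiation genes 3 rose, the cytokines Il10 (1.57 ± 0.38), Ifng (1.33 ± 0.37) and Il17a (1.13 ± 0.33), and 3 fell, the aryl hydrocarbon receptor Ahr (-1.78 ± 0.30) among them, with the same counts over the list alone. With batch as a block 2 rose and 1 fell, and Il17a, at 1.13, lost its call. Rab27a rose by 1.47 ± 0.18, 1 of 3 risen and 2 fallen of 39 vesicle trafficking genes (the same over the list alone). Of 25 memory and activation genes 3 rose and 3 fell (4 and 5 over the list alone). The memory list was not called, but was at 0.40 (adjusted p = 0.0475) within batch 2 and at 0.60 (0.0139) with 4 other-cell means, against 0.07 (0.75) with batch as a block and -0.10 (0.854) within batch 1. S100a6 changed by 1.52 ± 0.30, Anxa2 by 1.28 ± 0.26 (-0.12 on the deposited values) and the adhesion receptor Cd44 by -0.92 ± 0.16. Of 18 inhibitory receptor and exhaustion genes 1 rose, the repressor Prdm1 at 0.88 ± 0.25 (-0.42 on the deposited values), and 4 fell (2 and 5 over the list alone). The inhibitory ligand Cd200 changed by -1.47 ± 0.28 (-0.41 within batch 2) and the inhibitory receptor Btla by -1.15 ± 0.34, or by 0.41 within batch 2. Of 19 regulatory T-cell genes 2 rose and 3 fell (2 and 4 over the list alone), with Nrp1 at -2.31 ± 0.43. The actin regulator Evl changed by -2.0 ± 0.35 and was the 1 gene of 42 in the actin list that passed over all genes and over the list alone. The lactate dehydrogenase gene Ldha changed by 0.81 ± 0.18 (-0.41 on the deposited values), 1 of 2 glycolysis genes of 19 that rose (5 over the list alone). Adjusted p of the genes named here was at most 0.0237.

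Among the largest changes in CD4 T cells was that of the growth factor Hbegf, by -5.85 ± 0.29 (adjusted p = 8.79e-15). Its log2 level ran from 10.92 to 11.64 on the 6 WT arrays and from 4.31 to 6.87 on the 22 transgenic arrays. The cell cycle regulator Rgcc changed by -3.51 ± 0.37 (9.61e-07), the nuclear receptor Nr4a3 by -3.56 ± 0.57 (0.000171), Tbc1d4 by -2.93 ± 0.42 (5.88e-05), the repressor Bach2 by -2.76 ± 0.47 (0.000277) and the IgM receptor Fcmr by -2.77 ± 0.65 (0.00537). Higher in CLL were the immediate-early gene Ier3 (3.71 ± 0.48), Hp (3.37 ± 0.81), Smpdl3b (3.04 ± 0.52), Baiap3 (2.98 ± 0.55), Apobec2 (2.80 ± 0.57) and the myeloid gene Ms4a3 (2.54 ± 0.76), with adjusted p of at most 0.0255. With means of 4 other-cell lists as covariates, Hp was -0.062, Ms4a3 -1.22 and Fcmr 0.11. Ms4a3, at 2.55 with batch as a block, lost its call there. Within batch 2 Ms4a3 was 0.23, Fcmr -0.83 and Bach2 -1.40, and 14 of the 42 called genes named were smaller by over 1.5 times or turned.

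Markers of other cells moved with the CLL group in the CD4 samples. Of 15 neutrophil genes 12 rose and 0 fell (median 3.33, adjusted p = 1.19e-08, and 0.236 with estimated correlation), with the calprotectin genes S100a9 at 3.59 ± 0.77 and S100a8 at 3.33 ± 0.77. Of 14 erythroid genes 6 rose (median 1.49, adjusted p = 6.22e-06, and 0.323 with estimated correlation), and the carbonic anhydrase Car2 differed by 1.45 ± 0.55 (adjusted p = 0.0766). Of 21 B-cell genes 9 fell and 0 rose (median -1.42, adjusted p = 2.32e-11, and 0.212 with estimated correlation), Ighm differing by -0.41 ± 0.20 (adjusted p = 0.17). Of 10 plasma cell genes 6 fell and 1 rose (median -1.19, adjusted p = 4.09e-05, and 0.212 with estimated correlation), with the immunoglobulin joining chain Jchain at -2.59 ± 0.59. Of 12 dendritic cell genes 9 fell (median -1.48, adjusted p = 1.19e-08, and 0.0953 with estimated correlation), with Cd83 at -2.02 ± 0.49. Of 16 monocyte genes 2 fell (median -0.54, adjusted p = 0.0479, and 0.562 with estimated correlation), although the list median was 0.18 within batch 1. The counts over the list alone were 12 risen for neutrophils and 10 for erythroid cells, and 14 fallen for B cells, 8 for plasma cells, 9 for dendritic cells and 2 for monocytes.

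Mitochondrial respiration was higher as a list in this CD4 comparison (median 0.29, adjusted p = 9.35e-06, and 0.46 with estimated correlation), with 2 of 33 genes risen (6 over the list alone). Its median was -0.07 within batch 2 and -0.99 on the deposited values. Lower as lists were immediate-early genes (median -0.53), T-cell receptor signalling (-0.23), follicular helper T cells (-0.65) and the actin cytoskeleton (-0.15). Their adjusted p was 0.00139, 0.02, 0.0479 and 0.0479 in that order, and 0.46, 0.562, 0.46 and 0.596 with estimated correlation. Follicular helper and actin genes were not called with batch as a block (adjusted p = 0.0642 and 0.0628), nor was the monocyte list (0.136). Within batch 2 the medians were 0.10 for immediate-early, 0.46 for T-cell receptor signalling, -0.23 for follicular helper and 0.20 for actin genes. T-cell receptor signalling passed upward there (adjusted p = 0.0222). Actin genes passed upward with 4 other-cell means, at 0.26 (adjusted p = 0.0335), and T-cell receptor signalling was 0.42 (0.0653). Without the dim arrays these medians were 0.20 and 0.21. The direction of both depended on the fit.

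This comparison called 1559 of 11454 genes at adjusted p under 0.05 in limma, 783 higher and 776 lower. On the deposited values 0.3% of 6037 called genes were higher, with an all-gene median of -1.06. The count was 1450 with batch as a block, 1331 within batch 1 and 1 within batch 2 (2 WT and 2 CLL arrays), 960 without WT 1 and 994 without WT 3, 1388 without the dim arrays, and 4 with age as a covariate. Of the 1331 genes called within batch 1 alone 61.1% had the same sign within batch 2, and the changes of the 2 batches had r = 0.30 across all genes.

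**Figure D2:**
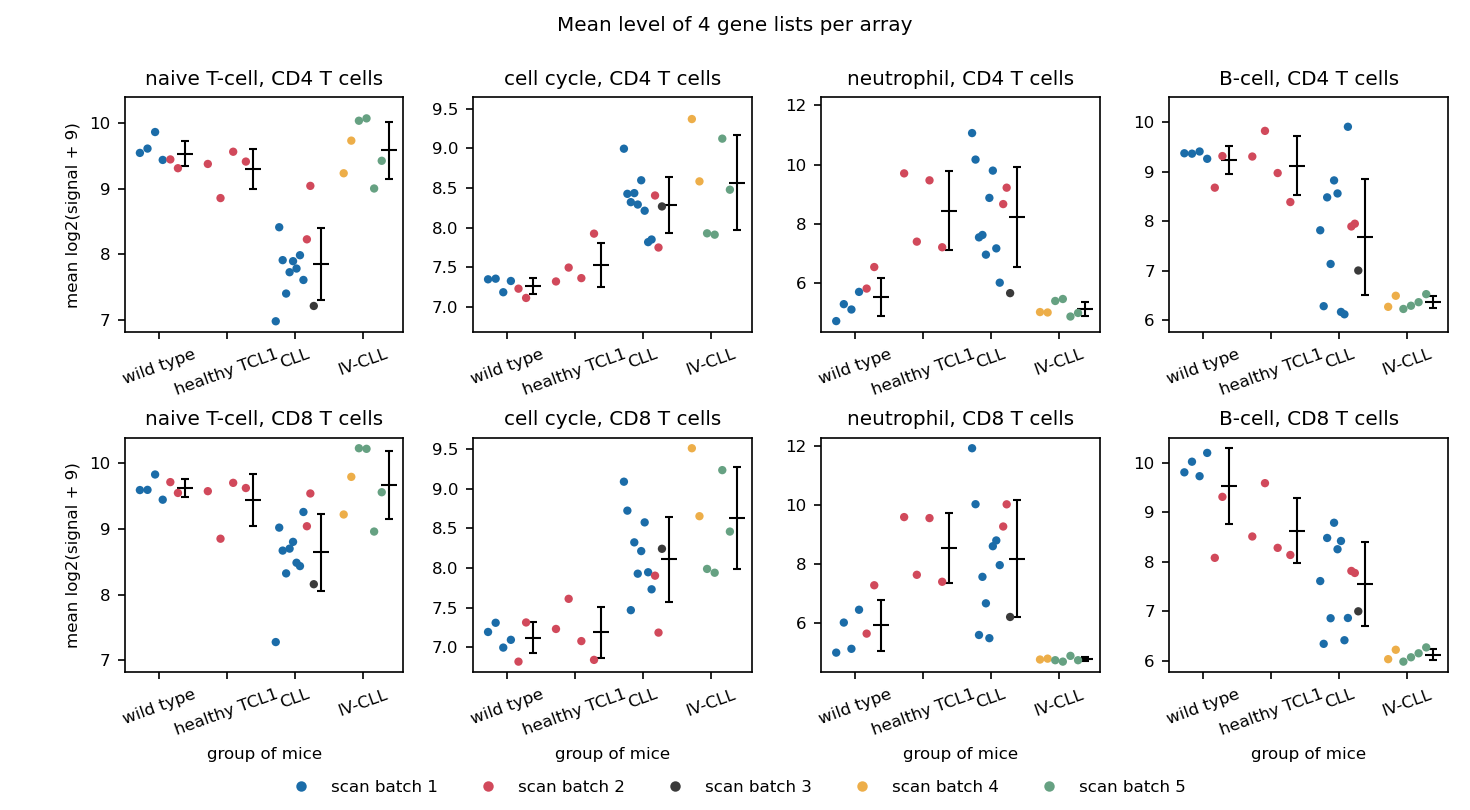
Mean log2(signal + 9) of the naive T-cell, cell cycle, neutrophil and B-cell lists on each array, CD4 above and CD8 below, by group, with black bars for the group mean ± SD.

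In CD8 T cells of mice with CLL (n = 12) against WT mice (n = 6), cell cycle and mitochondrial genes were higher and naive T-cell genes lower. Of 29 cell cycle genes 22 rose and 0 fell (24 and 0 over the list alone; median 0.98, adjusted p = 1.78e-11, and 0.342 with estimated correlation). The replication helicase subunit Mcm3 changed by 1.11 ± 0.21 (adjusted p = 0.00106), Ccna2 by 1.58 ± 0.33 (0.00236) and the mitotic regulator Birc5 by 1.42 ± 0.30 (0.00287). The list median was 0.92 with batch as a block, 1.06 within batch 1, 0.50 within batch 2 and 0.35 with 4 other-cell means, where 0 genes rose. Of 33 mitochondrial respiration genes 14 rose and 0 fell (18 and 0 over the list alone), although the list median was -0.42 on the deposited values, where the all-gene median was -0.69. The respiratory complex genes Sdhc and Uqcrc1 changed by 0.72 ± 0.16 and 0.72 ± 0.18, or by -0.20 and -0.16 on the deposited values, and the list had a median of 0.41, adjusted p = 1.83e-06, and 0.364 with estimated correlation. Of 19 glycolysis genes 6 rose and 0 fell (7 and 0 over the list alone), with Ldha at 1.18 ± 0.19 and Tpi1 at 1.15 ± 0.25. The glycolysis list had a median of 0.28, adjusted p = 0.00858, and 0.342 with estimated correlation, and a median of -0.51 on the deposited values. Within batch 2 the medians were 0.11 for mitochondrial and 0.22 for glycolysis genes, and Ldha was 0.22.

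Of 19 naive T-cell genes 9 fell and 1 rose in CD8 T cells (10 and 1 over the list alone), and the list had a median of -0.91, adjusted p = 3.68e-06, and 0.342 with estimated correlation. Ccr9 changed by -3.13 ± 0.46 (adjusted p = 6.75e-05) and Foxp1 by -1.29 ± 0.24 (0.000734). The median was -0.88 with batch as a block, -1.06 within batch 1 and -0.39 within batch 2, and -0.44 with 4 other-cell means, where 3 genes fell. Of 28 cytotoxic effector genes 7 rose and 1 fell, the same over the list alone (median 0.49, adjusted p = 0.135), with Gzmb at 2.06 ± 0.51, Gzmm at 2.25 ± 0.54 and Cst7 at 1.29 ± 0.26. Of 25 memory genes 6 rose and 1 fell (7 and 2 over the list alone; median 0.14, adjusted p = 0.117), S100a6 by 2.23 ± 0.33. Of 19 helper genes 1 rose, Tbx21 by 1.07 ± 0.31, and 2 fell, with Ahr at -2.63 ± 0.32. Of 39 vesicle genes 2 rose, with Rab27a at 1.47 ± 0.18, and 3 fell. Of 16 inhibitory receptor genes 4 fell and 0 rose (5 and 0 over the list alone; median -0.63, adjusted p = 0.00365, and 0.345 with estimated correlation), with Cd200 at -1.51 ± 0.31 and Btla at -1.36 ± 0.39. Within batch 2 the list median was 0.17, Cd200 was -0.46 and Btla -0.03. Cytotoxic, memory, T-cell receptor and interferon genes were not called here, with batch as a block or within batch 1. At correlation 0.01 they passed upward without the dim arrays, with 4 other-cell means and within batch 2 (2 arrays a group). Their batch 2 medians were 0.66 (adjusted p = 0.000295), 0.45 (0.000473), 0.24 (0.0172) and 0.35 (0.0068).

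Hbegf changed by -5.59 ± 0.31 (adjusted p = 3.36e-13) in CD8 T cells, from 10.97 to 11.34 on the WT arrays and from 3.86 to 7.40 on the transgenic arrays. Other large falls were Nr4a3 (-3.72 ± 0.84), Rgcc (-3.58 ± 0.40), Fcmr (-3.26 ± 0.67), Dapl1 (-3.23 ± 0.54), Rab30 (-3.0 ± 0.61), Hs3st1 (-2.90 ± 0.40) and H2-Ea (-3.03 ± 0.47). Large rises were Ier3 (3.10 ± 0.40), Hp (2.90 ± 0.87), Apobec2 (2.74 ± 0.45), Ms4a3 (2.71 ± 0.75), G0s2 (2.36 ± 0.40) and Nfe2 (2.27 ± 0.53). With means of 4 other-cell lists as covariates Ms4a3 was -1.43 and Fcmr 0.76, and with the B-cell mean as a covariate Fcmr was 0.11 and Rab30 0.051. H2-Ea lay from 8.15 to 8.89 on WT 1 to 4 (batch 1) and at 4.33 and 5.80 on WT 5 and 6 (batch 2). Within batch 2 H2-Ea was -0.92, Nr4a3 -1.99, Dapl1 -1.80, Rab30 -1.74, Fcmr -0.38 and Car2 0.28, and 19 of the 35 called genes named were smaller by over 1.5 times.

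Markers of other cells also moved with the CLL group in the CD8 samples. Of 22 B-cell genes 18 fell and 0 rose (median -1.82, adjusted p = 2.03e-17, and 0.0831 with estimated correlation), Ighm differing by -0.57 ± 0.21 (adjusted p = 0.0583). Of 10 plasma cell genes 6 fell (median -1.51, adjusted p = 1.83e-06, and 0.297 with estimated correlation), with Jchain at -2.93 ± 0.67. Of 12 dendritic cell genes 6 fell (median -1.48, adjusted p = 1.10e-06, and 0.08 with estimated correlation), with Cd83 at -3.21 ± 0.52. Of 17 monocyte genes 3 fell (median -0.84, adjusted p = 0.00206, and 0.368 with estimated correlation). Of 14 erythroid genes 10 rose (median 1.68, adjusted p = 2.52e-05, and 0.364 with estimated correlation), with Car2 at 1.76 ± 0.51. Of 15 neutrophil genes 5 rose (median 2.25, adjusted p = 4.21e-05, and 0.364 with estimated correlation), S100a9 differing by 2.25 ± 0.88 (adjusted p = 0.076). Over the list alone 21 B-cell, 7 plasma cell, 8 dendritic and 6 monocyte genes fell, and 10 erythroid and 11 neutrophil genes rose. Immediate-early (median -0.60), MAPK and NF-kB feedback (-0.28) and follicular helper genes (-0.75) were lower as lists. Adjusted p was 0.00164, 0.0247 and 0.0336 in that order, and 0.368, 0.368 and 0.364 with estimated correlation. Within batch 2 these medians were 0.37, 0.14 and -0.10. The MAPK list passed upward with 4 other-cell means, at 0.89 (adjusted p = 0.00807).

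In CD8 T cells 1983 of 11367 genes passed in limma, 1111 higher and 872 lower in CLL. On the deposited values 17 of 2451 called genes were higher. The count was 2122 with batch as a block, 1618 within batch 1 and 1 within batch 2, 1214 without WT 1, 2092 without the dim arrays and 9 with age as a covariate. Of the 1618 genes called within batch 1 alone 85% had the same sign within batch 2, with r = 0.46 across all genes.

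**Figure D3:**
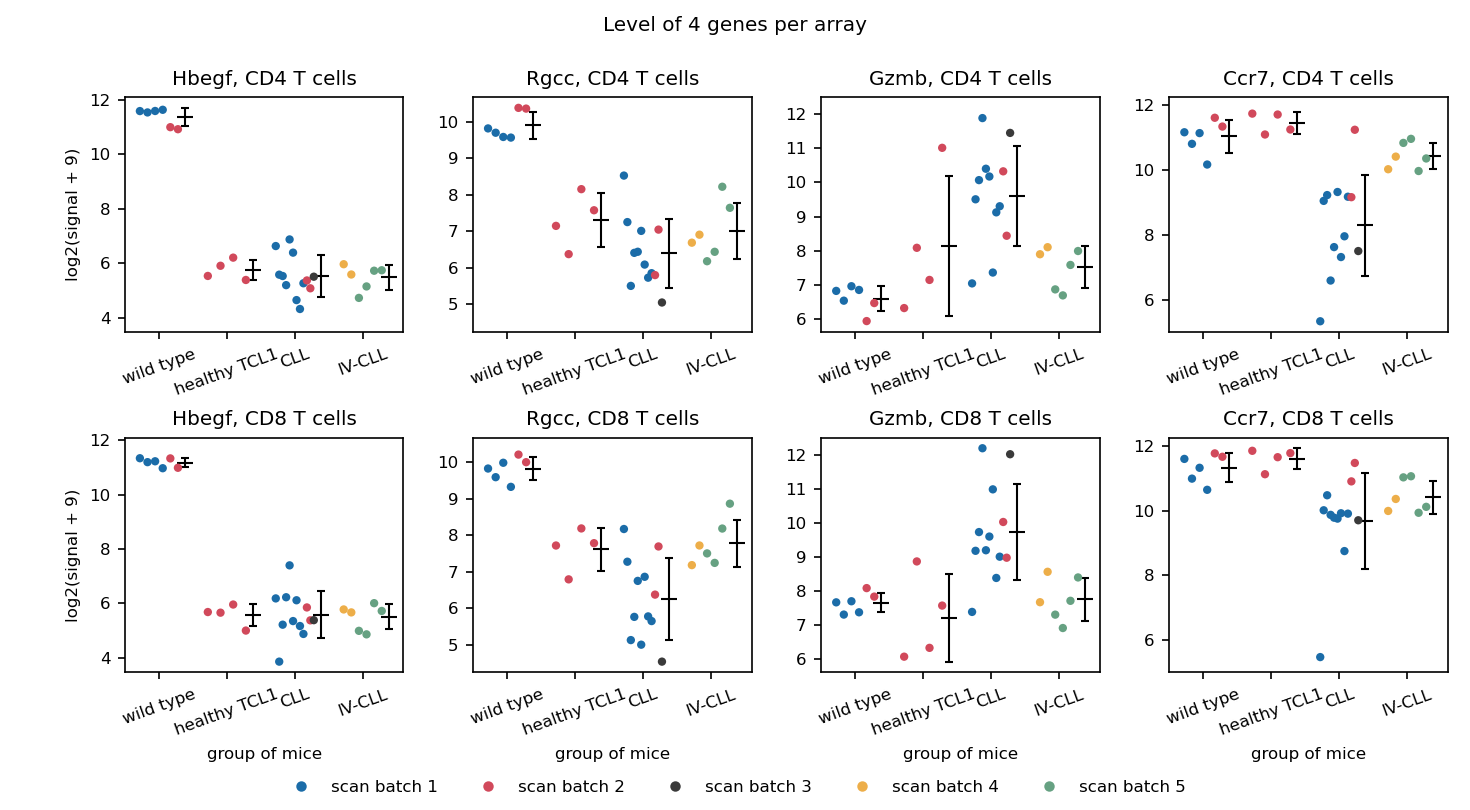
Log2(signal + 9) of Hbegf, Rgcc, Gzmb and Ccr7 on each array, CD4 above and CD8 below, by group, with black bars for the group mean ± SD.

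The CLL minus WT changes were compared between the cell types. CD4 and CD8 samples of 1 age and sex label had correlated residuals, so agreement between cell types also holds what mice and batches share. Across 10893 genes, which are not independent replicates, the CD4 and CD8 changes had r = 0.83. There were 450 genes higher in both (75.9 if the calls were independent), 473 lower in both (59.1) and 1 called in opposite directions (134.9). Aqp9 was the only gene whose change differed between the cell types in the fit that takes the CD4 and CD8 samples as independent, by 3.23 ± 0.56 (CD8 minus CD4, adjusted p = 0.00551), from -1.29 in CD4 and 1.93 in CD8, and it was chosen for its value. At an unadjusted p under 0.05 there were 357 genes. The count was 0 on the deposited values (all-gene median 0.37), with batch as a block and without WT mouse 2. It was 2 without the CLL mouse numbered 6 in CD4 and 7 in CD8, 6 without CLL mouse 1, 69 with the animal as a block (55 higher and 14 lower, Aqp9 among them) and 93 with the block by transcript sex.

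In CD4 T cells of mice with CLL (n = 12) against healthy transgenic mice (n = 4), a contrast that holds the transgene fixed, naive T-cell genes were lower and cell cycle genes higher. With batch as a block all gene calls of this contrast were lost. Of 19 naive T-cell genes 10 fell and 0 rose (13 and 0 over the list alone; median -1.25, adjusted p = 3.39e-11, and 0.0824 with estimated correlation). Ccr9 changed by -2.84 ± 0.37 (adjusted p = 0.000213), Dapl1 by -3.40 ± 0.49 (0.000288), Ccr7 by -3.16 ± 0.59 (0.00315) and Actn1 by -2.14 ± 0.38 (0.00225). Of 29 cell cycle genes 6 rose and 0 fell (20 and 0 over the list alone; median 0.79, adjusted p = 2.27e-11, and 0.213 with estimated correlation), although the list median was -0.38 on the deposited values, where the all-gene median was -0.98. Cdk1 changed by 1.44 ± 0.34, Mad2l1 by 1.34 ± 0.30 and Ccna2 by 1.16 ± 0.32 (-0.065 on the deposited values). The medians were -1.16 and 0.64 with batch as a block and -0.92 and 0.55 within batch 2, where Ccr7 was -1.25 and Actn1 -0.57. Of 18 inhibitory receptor genes 1 rose, Pdcd1 by 1.45 ± 0.39 (adjusted p = 0.0296), and 1 fell, Cd244a by -1.31 ± 0.34 (0.0256), or 1 and 2 over the list alone, and the list was not called (median -0.19, adjusted p = 0.583). Of 13 follicular helper genes 2 rose, with Sh2d1a at 1.65 ± 0.32 (0.00363), and 0 fell (4 and 2 over the list alone), in a list not called (median -0.004, adjusted p = 0.537). Ahr changed by -2.04 ± 0.35 (0.00141), the 1 called of 22 helper genes, Rab27a by 1.34 ± 0.21 (0.000675), the 1 risen of 39 vesicle genes with 1 fallen, and Dusp4 by -2.19 ± 0.57 (0.0267), 1 of 3 fallen of 25 MAPK genes.

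The largest falls in this contrast were Acod1 (-4.32 ± 0.66), Nr4a3 (-3.95 ± 0.66), Hcar2 (-3.74 ± 0.68) and Ptgs2 (-3.43 ± 0.64). The largest rises were Pld2 (1.86 ± 0.34), H3f3b (1.83 ± 0.53, or -0.33 with 4 other-cell means), Atp8b4 (1.81 ± 0.34) and Poglut2 (1.78 ± 0.42), with adjusted p of at most 0.0448. Within batch 2 Acod1 was -1.18, Hcar2 -1.16, H3f3b 0.54 and Dusp4 -0.70, but Pdcd1 1.74, Sh2d1a 1.75 and Ahr -2.02, and 14 of the 23 called genes named here were smaller by over 1.5 times. Cd4 differed by 0.03 ± 0.36 and Cd3e by 0.16 ± 0.27. Tyrobp changed by -1.75 ± 0.45. Of 16 monocyte genes 6 fell (12 over the list alone; median -1.82, adjusted p = 1.79e-09, and 0.186 with estimated correlation). Of 12 dendritic cell genes 5 fell (8 over the list alone; median -1.07, adjusted p = 5.49e-09, and 0.0824 with estimated correlation), with Cd83 at -2.35 ± 0.56. Of 21 B-cell genes 5 fell (13 over the list alone; median -1.49, adjusted p = 8.84e-10, and 0.213 with estimated correlation). Lower as lists too were plasma cell (median -0.69), platelet (-0.86), actin (-0.31), immediate-early (-0.47), regulatory T-cell (-0.41), MAPK feedback (-0.29) and vesicle genes (-0.21). Adjusted p of these was 0.0115, 0.00872, 0.00069, 0.00069, 0.0159, 0.0236 and 0.0236 in that order, and 0.458, 0.213, 0.512, 0.4, 0.505, 0.458 and 0.213 with estimated correlation. Mitochondrial respiration was higher (median 0.24, adjusted p = 0.000142, and 0.505 with estimated correlation), with a median of -1.05 on the deposited values. Erythroid genes were higher as a list (median 0.97, adjusted p = 0.00728, and 0.518 with estimated correlation). Within batch 2 the actin, MAPK feedback and vesicle medians were 0.09, 0.12 and 0.01, and the erythroid median was -0.06. Cytotoxic genes, not called here, passed upward there at 0.55 (adjusted p = 0.0111) and T-cell receptor genes at 0.39 (0.00049). Neither was called with batch as a block, and the actin, vesicle, regulatory, MAPK, immediate-early, erythroid and platelet lists lost their calls (adjusted p = 0.0712 to 0.45).

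This contrast called 511 of 11454 genes, 158 higher and 353 lower, against 1405 on the deposited values, of which 3 were higher. It called 0 with batch as a block (627 at unadjusted p under 0.05), 0 within batch 2 (1263) and 0 with age as a covariate (877). It called 250 without the dim arrays and 83, 303 and 127 without healthy mice 1, 2 and 3. Without CLL 11 and 12 it called 859 and 805.

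In CD8 T cells of mice with CLL (n = 12) against healthy transgenic mice (n = 4), Gzmb rose by 2.51 ± 0.59 (adjusted p = 0.0211), the 1 called of 28 cytotoxic genes (list median 0.09, adjusted p = 0.68). With batch as a block, where Gzmb was 2.46, this and all other gene calls of the contrast were lost. Among the largest rises, Haspin changed by 1.92 ± 0.35 (0.0061), Ncapg by 1.91 ± 0.39 (0.0121) and Fignl1 by 1.81 ± 0.39 (0.0129). Of 29 cell cycle genes 1 rose over all genes, Cdk1 by 1.76 ± 0.43, and 25 over the list alone (median 0.95, adjusted p = 4.76e-12, and 0.308 with estimated correlation). Of 19 naive T-cell genes 3 fell, with Ccr9 at -2.50 ± 0.53, Dapl1 at -2.37 ± 0.63 and S1pr1 at -1.41 ± 0.40. In that list 10 fell and 1 rose over the list alone (median -0.77, adjusted p = 0.00012, and 0.382 with estimated correlation). The medians were 0.58 for cell cycle and -0.37 for naive genes with batch as a block, and 0.39 and -0.10 within batch 2. Ahr changed by -2.41 ± 0.36, the 1 called of 19 helper genes, and Rab27a by 1.32 ± 0.21, the 1 risen of 39 vesicle genes with 1 fallen. The largest falls were Nr4a3 (-4.67 ± 0.97), Acod1 (-4.00 ± 0.84), Hcar2 (-3.64 ± 0.85) and Cxcl2 (-3.61 ± 0.96, or 0.48 with 4 other-cell means). Within batch 2 Nr4a3 was -1.38, Acod1 -0.21, Hcar2 -0.18, Cxcl2 -0.17 and Dapl1 -0.74, but Gzmb 2.29 and Ahr -2.35, and 10 of the 15 called genes named here were smaller by over 1.5 times. Cd8a differed by -0.77 ± 0.56 and Cd3e by 0.05 ± 0.34.

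Of 17 monocyte genes 8 fell in this CD8 contrast (14 over the list alone; median -1.86, adjusted p = 1.67e-10, and 0.19 with estimated correlation). Of 12 dendritic cell genes 4 fell (6 over the list alone; median -1.20, adjusted p = 2.22e-05, and 0.19 with estimated correlation), with Cd83 at -2.78 ± 0.60. Of 22 B-cell genes 3 fell (7 over the list alone; median -1.22, adjusted p = 2.59e-07, and 0.308 with estimated correlation). Plasma cell (median -0.57), inhibitory receptor (-0.70), immediate-early (-0.60), MAPK feedback (-0.35), actin (-0.21) and vesicle genes (-0.18) were lower as lists. Mitochondrial (0.29, or -0.41 on the deposited values) and erythroid genes (1.10) were higher. Adjusted p of these lists was 0.0225, 0.00127, 8.10e-05, 0.00127, 0.00658, 0.0379, 0.000153 and 0.00514 in that order, and 0.458, 0.308, 0.328, 0.308, 0.458, 0.308, 0.458 and 0.458 with estimated correlation. Within batch 2 the medians were 0.21 for immediate-early and 0.06 for actin genes. Not called here but upward within batch 2 were cytotoxic genes at 0.63 (adjusted p = 7.90e-06), T-cell receptor genes at 0.30 (0.00022) and neutrophil genes at 1.07 (0.000232), the last downward without the dim arrays at -1.94 (0.0243). With batch as a block cytotoxic genes were called (0.015), and the actin, vesicle, MAPK and immediate-early lists lost their calls (0.108 to 0.3). The contrast called 388 of 11367 genes, 143 higher and 245 lower, against 159 on the deposited values, of which 1 was higher, with an all-gene median of -0.54. It called 0 with batch as a block (599 at unadjusted p under 0.05), 0 within batch 2 (784) and 0 with age as a covariate (1247). It called 21, 52 and 155 without healthy mice 1, 3 and 4. Without CLL 4, 6, 11 and 12 it called 226, 256, 839 and 770.

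In CD4 T cells of healthy transgenic mice (n = 4) against WT mice (n = 6), the contrast of the transgene without disease, Hbegf fell and genes of the neutrophil list rose. With batch as a block Hbegf and Rpgrip1 kept their calls, but Rgcc, at -2.76, and the rises named here did not, and 0 genes of the neutrophil list rose. Hbegf changed by -5.63 ± 0.37 (adjusted p = 2.29e-11), Rpgrip1 by -2.80 ± 0.42 (0.000718) and Rgcc by -2.59 ± 0.48 (0.00778). Acod1 changed by 4.71 ± 0.73 (0.000918), Cxcl2 by 4.17 ± 0.79 (0.00788), Csf3r by 3.53 ± 0.64 (0.00743) and Hcar2 by 3.48 ± 0.76 (0.0304). Of 15 neutrophil genes 7 rose (11 over the list alone; median 3.19, adjusted p = 8.27e-18, and 0.15 with estimated correlation), with S100a9 at 5.03 ± 0.99 and S100a8 at 4.73 ± 0.99. The list median was 2.52 with batch as a block and 2.76 within batch 2. Monocyte genes were higher as a list (median 1.31, adjusted p = 1.82e-06, and 0.447 with estimated correlation), but passed downward within batch 2, at -0.62 (adjusted p = 0.0166), where Hcar2 was 1.15, Cxcl2 2.53, Csf3r 1.92, Acod1 3.56 and Rgcc -3.06. Cd4 differed by 0.06 ± 0.40 and Cd3e by -0.14 ± 0.31. No biology list had a member past the threshold over all genes. Follicular helper (median -0.55), T-cell receptor signalling (-0.14) and plasma cell genes (-0.60) were lower as lists. T-cell receptor genes passed upward with 4 other-cell means, at 0.45 (adjusted p = 0.00325). Cell cycle (0.28), glycolysis (0.33, or -0.03 within batch 2) and erythroid genes (0.30) were higher. Adjusted p of these lists was 0.000132, 0.031, 0.0468, 0.031, 0.0316 and 0.0468 in that order, and 0.166, 0.89, 0.723, 0.89, 0.599 and 0.89 with estimated correlation. Glycolysis, plasma cell and monocyte lists lost their calls with batch as a block (0.0648, 0.44 and 0.913). The contrast called 38 of 11454 genes, 24 higher and 14 lower. It called 5 with batch as a block (2 higher and 3 lower) and 2 within batch 2 (2 WT and 4 healthy arrays). It called 10 and 14 without healthy mice 1 and 3, and 25, 24, 24 and 22 without WT 1 to 4.

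In CD8 T cells of healthy transgenic mice (n = 4) against WT mice (n = 6), Hbegf changed by -5.60 ± 0.40 (adjusted p = 2.39e-10), Ppp1r21 by -2.38 ± 0.20 (1.39e-08), Rpgrip1 by -2.95 ± 0.43 (0.000374) and H2-Ea by -3.10 ± 0.61 (0.024). Ccr6, the 1 called of 19 helper genes, changed by -2.07 ± 0.46. The largest rises were Acod1 (4.49 ± 0.94), Neto2 (2.89 ± 0.42), Ier3 (2.39 ± 0.51) and G0s2 (2.34 ± 0.52), with adjusted p of at most 0.0444. With batch as a block none of these rises kept its call, nor did H2-Ea and Ccr6. Within batch 2 Neto2 was 2.21 (adjusted p = 0.0479), G0s2 2.12, Acod1 2.96, Ier3 1.35, Ccr6 -1.47 and H2-Ea -0.74. S100a9 differed by 4.20 ± 1.14 (adjusted p = 0.0989) and S100a8 by 3.85 ± 1.11 (0.119). Of 15 neutrophil genes 0 rose over all genes in limma and 11 over the list alone (median 2.97, adjusted p = 1.14e-07, and 0.705 with estimated correlation). The neutrophil list had a median of 1.62 with batch as a block and 2.53 within batch 2. Monocyte (median 1.27) and glycolysis genes (0.38) were higher as lists, and B-cell (-0.86) and plasma cell genes (-0.84) were lower. Their adjusted p was 0.00175, 0.00306, 1.48e-06 and 0.00351 in that order, and 0.714, 0.549, 0.705 and 0.714 with estimated correlation. The monocyte median was -0.54 and the B-cell median 0.002 within batch 2. Plasma cell and monocyte lists lost their calls with batch as a block (adjusted p = 0.148 and 0.698). Cd8a differed by 0.44 ± 0.63 and Cd3e by -0.02 ± 0.38. The contrast called 24 of 11367 genes, 7 higher and 17 lower, against 0 higher and 10 lower on the deposited values, where the all-gene median was -0.15. It called 4 with batch as a block (0 higher and 4 lower) and 5 within batch 2. Without WT 1 to 6 in turn it called 10, 9, 12, 10, 84 and 156. Without healthy mice 1 to 4 it called 12, 13, 11 and 8.

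In CD4 T cells of IV-CLL mice (n = 6) against healthy transgenic mice (n = 4), genes of effector function, inhibitory receptors and other blood cells were lower and cell cycle and erythroid genes higher. Of 18 inhibitory receptor and exhaustion genes 9 fell and 0 rose (11 and 0 over the list alone; median -1.20, adjusted p = 4.88e-07, and 0.0339 with estimated correlation). Entpd1 changed by -1.58 ± 0.26 (adjusted p = 0.000128) and Prdm1 by -1.94 ± 0.33 (0.00017). Of 28 cytotoxic effector genes 10 fell and 0 rose (12 and 0 over the list alone; median -0.94, adjusted p = 5.69e-09, and 0.0829 with estimated correlation). The chemokines Ccl3 and Ccl4 changed by -5.00 ± 0.66 and -3.06 ± 0.57 and Fasl by -2.44 ± 0.41. Of 19 regulatory T-cell genes 7 fell (12 over the list alone; median -1.05, adjusted p = 2.08e-08, and 0.0701 with estimated correlation), with Il10 at -2.71 ± 0.49 and Tnfrsf4 at -1.81 ± 0.28. Of 25 memory genes 9 fell, the same over the list alone (median -0.61, adjusted p = 4.33e-06, and 0.076 with estimated correlation), with the transcription factor Bhlhe40 at -3.67 ± 0.43 and Cd44 at -1.01 ± 0.21. The medians with 4 other-cell means were -1.58 for cytotoxic, -0.98 for regulatory, -0.70 for memory and 0.38 for cell cycle genes.

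Of 29 cell cycle genes 18 rose and 0 fell (25 and 0 over the list alone; median 1.09, adjusted p = 1.32e-11, and 0.101 with estimated correlation) in these CD4 T cells. The helicase subunit Mcm7 changed by 1.35 ± 0.25, Rrm2 by 1.84 ± 0.40 and Bub1 by 1.71 ± 0.36. Of 19 glycolysis genes 2 rose and 4 fell (3 and 6 over the list alone; median -0.42, adjusted p = 0.0566), with the glucose transporter Slc2a1 at -1.85 ± 0.27 and hexokinase Hk2 at -1.83 ± 0.35. Ahr changed by -2.91 ± 0.39, 1 of 3 fallen of 22 helper genes, and Prkcq by 1.94 ± 0.57, 1 of 2 risen and 1 fallen of 31 T-cell receptor genes. The helper (median -0.46), vesicle (-0.18), MAPK feedback (-0.50) and apoptosis lists (-0.04) were lower, although their medians were 0.22, 0.29, 0.078 and 0.54 on the deposited values, where the all-gene median was 0.63. Immediate-early genes were lower (median -0.63) and mitochondrial genes higher as a list (0.31). Adjusted p of these lists was 0.0122, 0.00725, 0.00099, 0.0493, 3.97e-06 and 0.00725 in that order, and 0.226, 0.076, 0.116, 0.13, 0.101 and 0.507 with estimated correlation. Cd4 differed by 0.47 ± 0.40, Cd3e by 0.20 ± 0.31 and Xist by 3.14 ± 1.70, and Cd8a changed by -2.26 ± 0.76 (adjusted p = 0.0448), a call lost with batch as a random block (-2.43), as was that of Ctsb below (-0.76).

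Markers of other cells moved with the IV-CLL group too. Of 16 monocyte genes 14 fell (median -3.41, adjusted p = 4.85e-17, and 0.0287 with estimated correlation), with Ctsb at -0.86 ± 0.24 and Cybb at -3.64 ± 0.47. Of 15 neutrophil genes 11 fell (median -3.15, adjusted p = 3.90e-10, and 0.092 with estimated correlation), with S100a9 at -8.17 ± 0.99. Of 21 B-cell genes 17 fell (median -2.75, adjusted p = 1.00e-16, and 0.0701 with estimated correlation), and Ighm differed by -0.27 ± 0.26. Of 12 dendritic cell genes 10 fell (median -2.51, adjusted p = 1.15e-11, and 0.0287 with estimated correlation), with Ly6d at -2.81 ± 0.74. Of 9 NK-cell genes 3 fell (median -0.37, adjusted p = 0.00182, and 0.076 with estimated correlation). Of 10 plasma cell genes 2 fell (median -0.47, adjusted p = 0.015, and 0.304 with estimated correlation), with a median of 0.14 on the deposited values, where the NK-cell median was 0.31. Of 14 erythroid genes 11 rose (median 3.27, adjusted p = 2.92e-10, and 0.076 with estimated correlation), with Car2 at 3.85 ± 0.71. Over the list alone 16 monocyte, 11 neutrophil, 18 B-cell, 10 dendritic, 4 NK-cell and 2 plasma cell genes fell and 12 erythroid genes rose. The largest falls were lysozyme Lyz1 (-6.18 ± 0.77), Cxcl2 (-5.49 ± 0.79), Acod1 (-5.34 ± 0.73) and Ccl3. The largest rises were Cldn13 (4.60 ± 0.84), Aldh1a1 (4.29 ± 0.72), Aqp1 (4.09 ± 0.86) and Ces2g (4.06 ± 0.69). With 4 other-cell means Cldn13 was -1.78, Aqp1 -1.46, Ces2g -0.054, Cxcl2 1.48 and Acod1 0.30. The contrast called 1568 of 11454 genes, 782 higher and 786 lower, against 652 on the deposited values, 71.8% of them higher. No batch held IV-CLL arrays and another group, so batch and group cannot be told apart. The IV-CLL arrays had like list means in pairs, numbers 1 and 5, 2 and 6, and 3 and 4 having CD4 erythroid means of 9.60 and 9.51, 8.34 and 8.42, and 7.17 and 7.28, so 6 arrays need not be 6 independent samples. With these pairs averaged 675 genes passed, and 693 with 1 and 2, 3 and 4, and 5 and 6 averaged. The count was 544 with the B-cell mean, 1369 with transcript sex, 816 with batch as a random block, 10 with the 4 other-cell means, 2665 without the dim arrays, 951 without healthy mouse 1 and 1045 without healthy 3.

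In CD8 T cells of IV-CLL mice (n = 6) against healthy transgenic mice (n = 4), inhibitory receptor and cytotoxic genes were lower and cell cycle genes higher. Of 16 inhibitory receptor genes 7 fell and 0 rose (9 and 0 over the list alone; median -1.61, adjusted p = 2.39e-07, and 0.0387 with estimated correlation). Entpd1 changed by -2.41 ± 0.32, the inhibitory receptor Havcr2 by -2.55 ± 0.56 and Prdm1 by -1.79 ± 0.36 (0.29 with 4 other-cell means). Of 28 cytotoxic genes 9 fell and 0 rose, the same over the list alone (median -0.81, adjusted p = 1.06e-06, and 0.124 with estimated correlation). Ccl3 changed by -3.86 ± 0.41, Ccl5 by -1.36 ± 0.23 and Fasl by -3.01 ± 0.49. Of 25 memory genes 9 fell, the same over the list alone (median -0.66, adjusted p = 7.99e-06, and 0.0686 with estimated correlation), with Bhlhe40 at -4.44 ± 0.61 and Cd44 at -1.33 ± 0.23. Of 15 regulatory T-cell genes 7 fell (8 over the list alone; median -1.16, adjusted p = 7.99e-06, and 0.0354 with estimated correlation). Of 29 cell cycle genes 23 rose and 0 fell (27 and 0 over the list alone; median 1.39, adjusted p = 9.50e-14, and 0.124 with estimated correlation). Mcm7 changed by 1.52 ± 0.26, Mcm5 by 1.49 ± 0.30 and Bub1 by 2.43 ± 0.44. Of 19 glycolysis genes 6 fell and 2 rose (9 and 3 over the list alone; median -0.52, adjusted p = 0.0121, and 0.124 with estimated correlation). Slc2a1 changed by -2.0 ± 0.29, pyruvate kinase Pkm by -1.22 ± 0.22 and Ahr by -3.35 ± 0.41. Adjusted p of these genes was at most 0.00206. The medians with 4 other-cell means were 0.39 for inhibitory receptor, -0.14 for cytotoxic, -0.29 for memory, 0.07 for regulatory and 1.17 for cell cycle genes, and plasma cell genes passed upward at 1.09 (adjusted p = 0.0243).

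In these CD8 arrays 16 of 17 monocyte genes fell (median -3.77, adjusted p = 2.48e-16, and 0.0354 with estimated correlation), with Mpeg1 at -3.85 ± 0.62. Of 15 neutrophil genes 11 fell (median -3.62, adjusted p = 2.09e-07, and 0.124 with estimated correlation), with S100a9 at -9.05 ± 1.14. Of 22 B-cell genes 15 fell (median -2.58, adjusted p = 2.77e-13, and 0.0686 with estimated correlation), and Ighm differed by -0.15 ± 0.27 (adjusted p = 0.747). Of 12 dendritic cell genes 8 fell (median -2.35, adjusted p = 2.45e-06, and 0.0387 with estimated correlation). Of 10 NK-cell genes 3 fell (median -0.67, adjusted p = 0.00075, and 0.0686 with estimated correlation). Of 14 erythroid genes 12 rose (median 3.6, adjusted p = 9.66e-11, and 0.0686 with estimated correlation), with Car2 at 4.70 ± 0.66 and Gfi1b at 4.26 ± 0.64. The counts over the list alone were 16 for monocytes, 11 for neutrophils, 16 for B cells, 9 for dendritic cells, 3 for NK cells and 12 for erythroid cells. Other large changes were Lyz1 (-6.68 ± 0.78), Il1r2 (-6.16 ± 0.99), Acod1 (-5.66 ± 0.94), Cxcl2 (-5.64 ± 1.07), C1qtnf12 (5.00 ± 0.70), Ces2g (4.82 ± 0.64) and Aldh1a1 (4.28 ± 0.62). With the 4 other-cell means Il1r2 was 0.50, Acod1 3.56, Cxcl2 4.89, C1qtnf12 -1.42, Ces2g -0.71, Aldh1a1 -0.32, Gfi1b -1.08 and Car2 -0.35. The helper (median -0.65), follicular helper (-0.93), MAPK feedback (-0.55), immediate-early (-0.82), actin (-0.15), platelet (-0.52) and plasma cell lists (-0.60) were lower. So were vesicle (-0.22) and apoptosis genes (-0.07), with medians of 0.18 and 0.36 on the deposited values, where the all-gene median was 0.42. Mitochondrial genes were higher as a list (median 0.31). Adjusted p of these lists was 0.00194, 0.0176, 0.00132, 2.22e-06, 0.0125, 0.0249, 0.0271, 0.0292, 0.0271 and 0.00446 in that order, and 0.124, 0.177, 0.141, 0.124, 0.414, 0.175, 0.414, 0.124, 0.0686 and 0.454 with estimated correlation. Vesicle genes lost their call with batch as a random block (0.0605). Helper, follicular helper, MAPK feedback, immediate-early and vesicle medians were 0.54, 0.92, 0.54, 0.39 and 0.39 with the 4 other-cell means. Cd8a differed by -0.03 ± 0.63, Cd3e by 0.15 ± 0.38 and Xist by 3.15 ± 1.68. The contrast called 2223 of 11367 genes, 1246 higher and 977 lower, against 919 on the deposited values, 68.6% of them higher. Batch and group cannot be told apart here either. The count was 1093 with the pairs of like arrays averaged (1114 by number), 1453 with age, 1830 with transcript sex, 1275 with batch as a random block and 0 with the 4 other-cell means (1142 at unadjusted p under 0.05), and no single array moved it by over 1.5 times.

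The IV-CLL minus healthy changes of CD4 and CD8 T cells had r = 0.93 across 10893 genes, with the same limit of shared mice and batches. By limma 617 genes were higher in both (86.8 if independent), 631 lower in both (68) and 0 in opposite directions (154.8). For CLL minus WT and IV-CLL minus healthy r across genes was 0.20 in CD4 and 0.30 in CD8 T cells. In CD4 121 genes were higher in both (53.5 if independent), 178 lower in both (53.3) and 73 in opposite directions (106.7), and in CD8 259 (121.8), 234 (74.9) and 78 (191.1).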

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

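Chosen only after the result was seen were the batch test of the genes that part WT from transgenic mice, and the fits without dim arrays, of batch 1 or batch 2 alone and with 4 other-cell means.

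In both cell types 8 genes had all 6 WT arrays on 1 side of all 22 transgenic arrays. These were Ap1s3, Habp4, Hbegf, Ngdn, Pik3ap1, Rgcc and Rpgrip1, higher in WT, and Mgst2, lower in WT, named after their values were seen (18 genes in CD4 and 22 in CD8). Of 100 choices of 6 arrays the highest other gave 0 in both, with no conclusion drawn, as CD4 and CD8 share mice and batches. The tables argue against carried-over B cells as the whole cause, since the difference with the B-cell mean as a covariate was 0.976 of the one without at the median over genes (lowest 0.394, for Pik3ap1 in CD8). They argue against array batch as the whole cause too, since of 162 genes that part WT mice outside batch 2, these 8 among them, 13 did so within it, where the other 27 choices of 2 arrays of batch 2 gave at most 5, although the median ratio of the 162 was 0.191. Open are the transgene itself, not tested, and stretches of chromosome that differ between the strains. Of these 8 genes 0 pairs lay within 20 tested genes of each other (random median 0). The closest lay 26 apart on chromosome 14, which holds Ngdn, Rgcc and Rpgrip1 (1242 of 10000 random sets came as close).

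Naive T-cell genes fell in CLL minus WT, and the list call held with an estimated correlation in CD4 (adjusted p = 0.0264) but not in CD8 (0.342). Without dim arrays the list median was 1.08 of the whole in CD4 (0.788 to 1.278 leaving out 1 array), so they do not account for the fall there. In CD8 it was 0.738 (0.503 to 0.867), so they may account for part. Batch 2 alone kept 0.59 in CD4 (0.159 to 0.798) and 0.434 in CD8 (0.127 to 0.702), with 2 arrays a group, and batch 1 kept 1.16 and 1.17, so batch differences are not the whole cause. With 4 other-cell means the ratio was 1.075 in CD4 (0.758 to 1.233), which argues against carried-over cells there, and 0.483 in CD8 (0.113 to 0.771), where they may account for part and stay open. Age goes with the group and stays open (ratio 0.851 in CD4 and 0.713 in CD8 with age as a covariate, 0 genes called by limma).

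Inhibitory receptor and exhaustion genes fell in IV-CLL minus healthy in both cell types. Against WT arrays of batch 1, which held fewer monocyte and neutrophil transcripts than the healthy mice, the fall was about as large. The median was 0.982 of the whole in CD4 (0.9 to 1.086) and 1.043 in CD8 (1.005 to 1.104). These WT arrays had monocyte means above IV-CLL (6.65 against 5.55 in CD4, 6.68 against 5.14 in CD8), so those cells are not excluded. With the B-cell mean as a covariate the ratio was 1.037 in CD4 and 0.951 in CD8, against B cells as the whole cause. With 4 other-cell means together it was 1.08 in CD4 and -0.24 in CD8 (median 0.39), so other cells stay open in CD8. Array batch cannot be told apart from the group (0.942 and 0.921 with a random block), and age is open too, since the IV-CLL mice were 3 months old.

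Single arrays stood apart from the rest of their group by Dixon's gap test (chance gives about 1 in 20 groups). The groups of 12 CLL arrays were not tested, although they hold arrays such as CD8 CLL 1, 2 and 8, low in Cd8a. The GAPDH 3' to 5' ratio of CD8 WT 5 was 0.789, below the others. In CD4 WT 5 the immediate-early mean log2 was 10.96, above, and the B-cell mean 8.68, below. In CD4 IV-CLL 6 the stroma mean was 5.28, above. In CD8 WT 6 the actin mean was 10.41 and the erythroid mean 5.54, both above. In CD8 WT 5 the apoptosis mean was 7.63 and the dendritic mean 7.19, both below. In CD8 healthy mouse 4 the vesicle mean was 8.20, below, and Cd3e 10.98, above, and in CD8 healthy mouse 2 the naive T-cell mean was 8.85, below. These were 1 of 24 tests of array measures (1.2 by chance), 9 of 162 of list means (8.1) and 1 of 21 of target genes (1). Among named genes 64 of 1236 tests stood apart, where chance gives 61.8.

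The CLL minus WT change differed between CD8 and CD4 for Aqp9, by 3.23. It differed by a list median of 0.56 for naive T-cell genes (adjusted p = 5.03e-07, and adjusted p = 0.53 with an estimated correlation), -0.35 for inhibitory receptors (0.00903 and 0.53), 0.29 for the interferon response (0.0379 and 0.932) and -0.47 for B-cell genes (0.00335 and 0.932). Probe sets without a single gene symbol, outside the comparisons, also passed in CLL minus WT, 309 of 4450 in CD4 (106 higher, 203 lower) and 459 of 4422 in CD8 (155 higher, 304 lower), or 6.9% and 10.4% against 10.7% and 14.2% of named probe sets.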

How the results depend on the processing

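Brightness, 4 other-cell means, leaving out dim arrays, 1 batch alone and averaged IV-CLL arrays were chosen after seeing the data. So was sex from transcripts, also in the animal block, and all other settings were planned. The cause was not tested for the changes below, except where fewer arrays were fitted. Of the results for named genes 6454 kept direction and side of the threshold, 796 lost the call, 33 gained it and 32 turned. Of 188 called gene results, 119 kept their call on the deposited values, 78 with age, 133 with the B-cell mean and 132 with the batch block. There were 172 without the dim arrays, 188 with array weights, 46 of 187 with 4 other-cell means and 7 of 133 in batch 2 alone. The series table gave no separate fit.

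In CD4 CLL minus WT the count of 1559 became 6037 on the deposited values, 982 with only the groups compared, 4 with age, 819 with the B-cell mean, 3460 with array weights, 3121 with the replicate block, 897 with brightness, 594 with 4 other-cell means and 1 in batch 2 alone. It stayed within 1.5 times of 1559 with both pseudocounts, both filters, the probe-set mean, both sex terms, the batch block, without the dim arrays and in batch 1 alone (1256 to 1624 over filters and pseudocounts). For CD8 CLL minus WT the count of 1983 became 9 with age, 981 with the B-cell mean, 3702 with weights, 1182 with brightness, 521 with 4 other-cell means and 1 in batch 2 alone.

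In CD4 CLL minus healthy the count of 511 became 1405 on the deposited values, 117 with only the groups compared, 0 with age (877 at an unadjusted p under 0.05 in limma), 152 with the B-cell mean, 1317 with weights, 0 with the batch block (627), 1925 with the replicate block and 250 without the dim arrays. It was 161 with brightness, 0 with 4 other-cell means (807) and 0 in batch 2 alone (1263). For CD8 CLL minus healthy 388 became 159 on the deposited values, 16 with only the groups compared, 0 with age (1247), 699 with the B-cell mean and 1614 with weights. It was 0 with the batch block (599), 1533 with the replicate block, 113 with brightness, 0 with 4 other-cell means (941) and 0 in batch 2 alone (784).

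In CD4 healthy minus WT 38 became 78 with only the groups compared, 2497 with weights, 5 with the batch block, 94 with the replicate block, 113 without the dim arrays and 2 in batch 2 alone. For CD8 healthy minus WT 24 became 10 on the deposited values, 10 with pseudocount 0.9, 46 with pseudocount 36, 15 with no filter and 45 with the probe-set mean. It became 144 with only the groups compared, 52 with age, 12 with the B-cell mean, 2406 with weights and 4 with the batch block. It was 55 with the replicate block, 165 without the dim arrays, 66 with brightness, 63 with 4 other-cell means and 5 in batch 2 alone.

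In CD4 IV-CLL minus healthy 1568 became 652 on the deposited values, 2773 with only the groups compared, 544 with the B-cell mean, 3581 with weights, 816 with the batch block, 2665 without the dim arrays, 10 with 4 other-cell means, 693 with IV-CLL arrays averaged as 1 and 2, 3 and 4, 5 and 6, and 675 as 1 and 5, 2 and 6, 3 and 4. For CD8 IV-CLL minus healthy 2223 became 919 on the deposited values, 1453 with age, 4127 with weights, 1275 with the batch block, 0 with 4 other-cell means (1142) and 1114 and 1093 with the same averages.

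The count of 1 for the difference between cell types became 0 on the deposited values (96 at an unadjusted p under 0.05 in limma), 3 with pseudocount 36, 0 with only the groups compared (236), 3 with sex, 0 with age (197) and 0 with the B-cell mean (400). It was 102 with weights, 0 with the batch block (336), 30 with the replicate block, 69 with the animal block, 93 with the animal block and transcript sex, 13 without the dim arrays and 0 in batch 1 alone (227). The replicate number does not pair samples across cohorts (r of residuals as low as -0.32), so the replicate block is not a paired test.

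Leaving out each mouse in turn gave 960 to 1797 for CD4 CLL minus WT, 83 to 859 for CD4 CLL minus healthy, 10 to 42 for CD4 healthy minus WT, 951 to 1506 for CD4 IV-CLL minus healthy. In CD8 the same order gave 1214 to 2242, 21 to 839, 8 to 156 and 1634 to 2212. The difference gave 0 to 6.

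Some directions turned on the deposited values. In CD4 CLL minus WT these were Anxa2 (-0.12), Prdm1 (-0.42), Ldha (-0.41), cell cycle (list median -0.25) and mitochondrial respiration (-0.99), and in CD4 CLL minus healthy Ccna2 (-0.065), cell cycle (-0.38) and mitochondrial respiration (-1.05). In CD4 IV-CLL minus healthy they were the medians of vesicle trafficking (0.29), helper (0.22), MAPK feedback (0.078), apoptosis (0.54), plasma cell (0.14) and NK-cell genes (0.31). In CD8 CLL minus WT they were Sdhc (-0.20), Uqcrc1 (-0.16), mitochondrial respiration (-0.42) and glycolysis (-0.51), in CD8 CLL minus healthy mitochondrial respiration (-0.41), and in CD8 IV-CLL minus healthy vesicle trafficking (0.18) and apoptosis (0.36).

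With the B-cell mean as a covariate, which takes out that list by construction, the B-cell median turned to 0.248, 0.043 and 0.067 in CD4 CLL minus WT, CLL minus healthy and IV-CLL minus healthy, and to 0.348, 0.073 and 0.034 in CD8 CLL minus WT, healthy minus WT and IV-CLL minus healthy. The plasma cell median turned to 0.34 in CD4 and 0.71 in CD8 IV-CLL minus healthy and to 0.028 in CD8 CLL minus healthy. Fcmr (0.11) and Rab30 (0.051) turned in CD8 CLL minus WT.

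With 4 other-cell means as covariates, Hp (-0.062), Ms4a3 (-1.22), Fcmr (0.11) and Car2 (-1.09) turned in CD4 CLL minus WT, Ms4a3 (-1.43), Fcmr (0.76) and Car2 (-0.73) in CD8 CLL minus WT, H3f3b (-0.33) in CD4 CLL minus healthy and Cxcl2 (0.48) in CD8 CLL minus healthy. In CD4 IV-CLL minus healthy Cldn13 (-1.78), Aqp1 (-1.46), Ces2g (-0.054), Cxcl2 (1.48) and Acod1 (0.30) turned. In CD8 IV-CLL minus healthy C1qtnf12 (-1.42), Ces2g (-0.71), Aldh1a1 (-0.32), Gfi1b (-1.08), Il1r2 (0.50), Acod1 (3.56), Cxcl2 (4.89), Prdm1 (0.29) and Car2 (-0.35) turned. In batch 2 alone Btla (0.41) turned in CD4 CLL minus WT.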

Other observations

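Of the tests in this part, the splits of averaged arrays and the fits of 1 batch alone, with 4 other-cell means and of the animal block with sex from transcripts were chosen only after the result was seen. In CD4 CLL minus WT these lists did not pass camera: MAPK and NF-kB feedback (median -0.18, adjusted p = 0.0927), interferon response (-0.02, 0.855), apoptosis (0.09, 0.562), heat shock (-0.07, 0.723), NK cell (-0.65, 0.11), platelet (-0.31, 0.269) and stroma genes (0.38, 0.233). Nor did vesicle, helper, inhibitory receptor, regulatory and glycolysis genes, with adjusted p = 0.284, 0.11, 0.309, 0.11 and 0.0573. Of these, interferon genes passed upward with 4 other-cell means, at 0.37 (adjusted p = 0.0335), apoptosis genes upward within batch 2, at 0.24 (0.0475), platelet genes downward within batch 2, at -0.81 (0.0124), and within batch 1 MAPK genes downward, at -0.26 (0.0266), and glycolysis genes upward, at 0.50 (0.0127). In CD8 CLL minus WT these were helper (0.25, 0.97), vesicle (-0.16, 0.153), T-cell receptor signalling (-0.09, 0.223), interferon response (0.28, 0.117) and actin genes (-0.005, 0.406). Regulatory (-0.15, 0.229), apoptosis (0.07, 0.587), heat shock (-0.20, 0.438), NK cell (-0.14, 0.22), platelet (0.25, 0.507) and stroma genes (0.24, 0.507) did not pass either. Of the first 5 all but vesicle genes passed upward with 4 other-cell means, at 0.88 (adjusted p = 0.00217) for helper, 1.14 (5.26e-08) for T-cell receptor, 1.65 (2.75e-09) for interferon and 0.32 (0.00513) for actin genes, also upward within batch 2 (0.18). For heat shock the median (-0.07 in CD4, -0.20 in CD8 CLL minus WT) and the mean (0.02 and 0.02) differed in sign, and the test pointed down.

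Median, mean and test also differed in sign for some uncalled lists of the other contrasts. In CD4 these were memory, follicular helper, apoptosis and glycolysis genes in CLL minus healthy, helper, memory and inhibitory receptor genes in healthy minus WT, and follicular helper and T-cell receptor genes in IV-CLL minus healthy. In CD8 they were apoptosis genes in CLL minus WT, interferon, apoptosis and glycolysis genes in CLL minus healthy, follicular helper, apoptosis and stroma genes in healthy minus WT, and heat shock genes in IV-CLL minus healthy. The naive T-cell list was not called in IV-CLL minus healthy, with a median of 0.62, adjusted p = 0.344 in CD4 and a median of 0.35, adjusted p = 0.549 in CD8, but in CD4 it passed upward with 4 other-cell means, at 1.03 (adjusted p = 0.000616).

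The arrays of each contrast were split at random into groups of the same sizes, 100 splits with the real one. In CD4 CLL minus WT 1 split, the real one, gave 1559 genes and the highest other 890, and in CD8 1 gave 1983 and the highest other 287, so chance can be excluded for both. The same holds for IV-CLL minus healthy, with 1568 against 913 in CD4 and 2223 against 1690 in CD8, which take the 6 IV-CLL arrays as independent. With like arrays averaged 1 of 35 splits, the real one, gave 675 and the highest other 206 in CD4, and in CD8 1 gave 1093 and the highest other 78. In CD4 CLL minus healthy 3 of 100 splits gave at least 511 genes, the highest 1297, and in CD8 3 gave at least 388, the highest 870. That share is under 0.05, but other splits gave more genes, so chance is not firmly excluded. Nor is array batch, since the splits ignore it and both cell types gave 0 genes with batch as a block or within batch 2. The highest splits, with over 2 times the real count, point to a structure among the CLL arrays. In CD4 they set apart CLL 1, 2, 5 and 7, dim arrays with the highest actin 3' to 5' ratios in CLL (1.53 to 2.16). In CD8 they set apart CLL 1, 2 and 8, all low in Cd8a, and healthy mouse 1. In CD4 healthy minus WT 2 of 100 splits gave at least 38 genes, and the highest, 784, set WT 1 to 4, which are batch 1, against the rest, which are batch 2, so that structure follows the batch. Within batch 2 the count was 2, and with batch as a block 5. In CD8 healthy minus WT 2 of 100 gave at least 24, the highest other 47. For the difference between cell types 12 of 100 splits gave at least 1 gene, the highest 37, so chance cannot be excluded for that count. The splits and the count of 1 take the CD4 and CD8 samples as independent. With the animal as a block 69 genes passed, or 93 with sex from transcripts, and no splits were made for those fits. The closest arrays of 1 group were IV-CLL 3 and 4, whose differences had an SD of 0.30 in CD4 and 0.29 in CD8, and all were kept as separate samples.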
